A study of Mus musculus with 6 samples.

How the data were processed

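Gene expression was measured in adrenal medulla microdissected from 12 µm cryosections of the adrenal glands of male mice, 8 weeks after transverse aortic constriction (TAC, a narrowing of the aorta that loads the heart with pressure) or after a sham operation. Each of the 6 Affymetrix Mouse Genome 430 2.0 arrays, 3 per group, held amplified RNA from both medullae of 1 animal, per the labels' protocols, so the replicates are separate animals. RNA was amplified in 2 cycles from the 3′ end, per the labels' protocols, and each gene is read by 1 or more probe sets, groups of short probes that mostly lie near the 3′ end of the transcript.

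The deposited table holds 1 intensity value per probe set and array, on a linear scale and already corrected for background. GCRMA is named in the submitters' processing notes, and its version and options are not given in the sources used here. The 6 columns did not share 1 distribution. The median intensity per array lay between 9.14 and 10.9, the 75th percentile between 50.8 and 73.0, and log2 values of at least 4 were reached by 17428 to 18413 probe sets per array. The values were used as deposited after a log2 transformation, and other scalings between arrays were tried as alternatives. The number of arrays limits the precision. The median standard error of a difference between groups was 0.39 on the log2 scale.

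Of 45101 probe sets, 64 were array controls and were left out of all tests. GEO's platform annotation gave 1 gene symbol for 34945 of the others, several for 932 and none for 9160, and no gene was named from a probe set with several symbols. The Entrez identifiers of 34741 probe sets were found in a RefSeq gene table of assembly GRCm38.p6, which updated 0 symbols. No coordinates are given because the table of values names no genome build.

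Probe sets at log2 4 or more on at least 3 of the 6 arrays were kept, whatever their group. This left 18188 probe sets, 15646 of them with 1 symbol, for 10178 genes. TAC and sham were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2-sided, no covariate, 4 residual degrees of freedom), and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Where a gene had several probe sets, the one with the highest mean over the 6 arrays stood for it. The other tested probe sets of the genes named in the text were also examined for direction.

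Before the data were examined, 30 gene lists were fixed, covering secretion by chromaffin cells (the hormone-releasing cells of the medulla), signalling and stress pathways, and markers of other cells that dissected medulla can hold. The 27 lists with at least 5 measured members were tested with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera asks whether a list's genes shifted relative to all other genes. It was repeated with an estimated correlation between list members, which allows for genes that vary together. Fry was run as an alternative and asks whether a list's genes move, on balance, one way or, in its mixed form, in either direction. Adjusted p-values over the list alone were also computed for each list's members.

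The genes named in the text followed a rule set in advance. Its first part took up to 12 genes per direction past the threshold, filled to 8 per direction by the smallest unadjusted p among genes without overlap between groups if fewer passed, passing over clone names, predicted genes and expressed sequence tags. The other parts took every member of the catecholamine synthesis list, the 2 members with the smallest p in each other list, and 15 genes of catecholamine and steroid production whatever their values. Of these, Grk2 is not analysed here, and Adra2c and Cyp11b2 stayed below the filter. Other genes were chosen after their values were seen, as the text says where they appear.

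RNA integrity was followed by the log2 difference between the 3′ and 5′ control probe sets of Gapdh and beta-actin, which is larger where transcripts are shortened. Carry-over of adrenal cortex was followed by the mean of a list of steroid-producing cell markers. Group differences of such array measures were tested with exact 2-sided permutation tests, which cannot go below p = 0.1 with 3 against 3 arrays. Poly-A spike-in controls are bacterial transcripts added before amplification, and hybridisation controls are added before hybridisation.

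The procedure was tested on simulated data for TAC against sham with the real spread of 18188 probe sets, 200 of them changed, in 10 draws. It recovered 0% of 2-fold and 5.9% of 4-fold changes with independent noise, and 0.8% and 21.4% when a component shared by probe sets, with a random score for each array, was simulated. The mean was 0.6 false calls per draw. A simulated shifted list of 20 genes was called by camera in 100% of draws at the preset correlation, and with an estimated correlation in 70% with independent noise and 10% with the shared component. For a list simulated in this way, the loss of a call with an estimated correlation is weak evidence against a shift. The simulated members were drawn at random and all shifted by the same amount. Members of the tested lists moved in both directions, so these rates do not give the power for those lists. Lists of random genes were called in 0% and 0.5% at the preset correlation, which does not test lists whose genes vary together. The alternatives were other filters, scalings, floors, probe set averaging, variance priors, array weights (by the gene-by-gene method, as the default REML method did not converge), covariates, blocks and thresholds, and leaving out each array in turn.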

Results

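Adrenal medulla from 3 mice after TAC and 3 mice after sham surgery was profiled 8 weeks after the operation, with 1 array per animal. The medulla releases adrenaline and noradrenaline, and its dissection can carry along cortex, vessels, connective tissue, nerve and glia, whose marker genes were therefore followed beside those of chromaffin cells. The median tested probe set lay between 6.31 and 7.01 on the log2 intensity scale in the 6 arrays. All values below are log2 intensities or differences of TAC minus sham on that scale, with n = 3 arrays per group. SD is the spread between arrays and SE the standard error of the limma fit.

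TAC and sham were compared to find genes whose expression in the medulla differs under cardiac pressure overload, and no gene passed the threshold. Rbfox3, which encodes a neuronal splicing factor, measured 8.54 ± 0.12 (SD) after TAC and 7.01 ± 0.05 after sham, 2.89-fold higher (difference 1.53 ± 0.21 SE, limma adjusted p = 0.384). Rbfox2, whose product is a splicing factor of the same family, was below the log2 4 filter in all TAC arrays and measured 5.10 ± 0.44 after sham. Its computed difference of -2.25 (adjusted p = 0.384) is therefore unreliable in size, and it was -1.10 with values under log2 4 set to 4. Kcnh2, a potassium channel gene, measured 7.63 ± 0.05 against 6.15 ± 0.13 (difference 1.49 ± 0.21 SE, adjusted p = 0.384). Map1b, which encodes a microtubule-associated protein of neurons, measured 4.23 ± 0.30 against 5.96 ± 0.53 (difference -1.73 ± 0.35 SE, adjusted p = 0.418). The other higher genes of the first part of the naming rule were Rhof (1.85), Phc2 (1.82), Myh9 (1.83), Sf3a2 (2.18), Srebf1 (1.72) and Pkdcc (2.08), each with an adjusted p of 0.384. The other lower genes were Plcxd3 (-2.14), Rgs7bp (-1.65), Smim11 (-1.50), Rdh11 (-2.01), Cldnd1 (-2.06) and Hmgb3 (-1.32), with adjusted p-values from 0.384 to 0.465. All TAC values of Plcxd3 and 2 of 3 of Rgs7bp were below log2 4, so their differences are unreliable in size, and they were -1.88 and -1.21 with such values set to 4. In all 16 genes the 3 arrays of one group lay above the 3 of the other, which the rule required.

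In limma, 0 of 18188 probe sets had an adjusted p under 0.05 and 0 under 0.10, and the smallest adjusted p was 0.384. At an unadjusted p under 0.05 there were 1263 probe sets, 6.94% of those tested, where 909 are expected by chance. Of these, 846 were higher and 417 lower after TAC, a share of 67.0% higher that was 50.7% with arrays centred on their medians, 56.6% after quantile normalization and 43.3% after cyclic loess. Without sham 1 the direction turned, with 945 higher and 1484 lower (38.9% higher), and with array weights 40.9% were higher. The groups did not overlap at 2368 probe sets, or 13.0%, where chance gives 10%. The unadjusted count was 2429 without sham 1, 641 without sham 2, 773 without sham 3 and 695 without TAC 3. With array weights, 6698 probe sets had an adjusted p under 0.05. The weights were 0.143 for sham 1, 2.73 for sham 2 and 2.96 for sham 3. They were 0.396 for TAC 1, 0.357 for TAC 2 and 6.11 for TAC 3, so the TAC side rested mostly on TAC 3. These weights came from limma's gene-by-gene method, because its default method did not converge.

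Different probe sets of 1 gene often disagreed, which bears on several genes named here. Myh9, a non-muscle myosin heavy chain gene, was read at 1.83, 0.34, -1.32 and -2.16 by 4 probe sets. Rhof was read at 1.85 and -0.60, Rbfox3 at 1.53 and -0.20, and Map1b at -1.73 and 0.81. The 3 probe sets of Calr, which encodes the chaperone calreticulin, lay at 0.88, 0.85 and 0.96. Of 38 named genes with several tested probe sets, 19 had both signs. Opposite in sign to the values given below were readings of Adm (-0.85), C1qb (-0.53), Cplx2 (-0.39 and -0.15), Eng (-0.09), Ern1 (-0.05 and -0.19) and Grk6 (-0.16). So were readings of Pdk1 (-0.11), Slc18a1 (-0.62), Socs3 (-0.04), Tsc22d3 (0.13) and Zbtb16 (-0.37), and those of catecholamine synthesis genes are given with them. Over 3647 genes, 8181 pairs of probe sets of the same gene shared their sign in 54.8%. Among the 113 pairs in which both had an unadjusted p under 0.05, 98 shared it, or 86.7% (exact 95% interval 79.1 to 92.4). The interval treats the pairs as independent, although they come from 77 genes and share the same arrays.

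None of the 10 measured catecholamine synthesis genes passed the threshold, and Th, Ddc, Dbh and Pnmt were abundant in both groups, with means from 12.38 to 14.40. Th, which encodes the rate-limiting enzyme of catecholamine synthesis, measured 13.12 ± 0.72 after TAC and 13.42 ± 0.31 after sham (difference -0.30 ± 0.42 SE, limma adjusted p = 0.981). Dbh, which makes noradrenaline, differed by 0.42 ± 0.26 (adjusted p = 0.886), and Pnmt, which converts noradrenaline to adrenaline, by 0.27 ± 0.21 (adjusted p = 0.939). Ddc, the decarboxylase that makes dopamine, differed by -0.51 ± 0.82 (adjusted p = 0.983). The cofactor genes Gch1 (0.30), Pts (0.03), Spr (-0.37), Qdpr (0.14) and Pcbd1 (0.16) and the granule cytochrome gene Cyb561 (-0.05) had adjusted p-values from 0.982 to 0.998. Other probe sets differed from these values. Pnmt also read -1.14 and 1.63, Ddc also read 0.83, Dbh also read -0.04 and -0.51, and Qdpr also read -0.83. Of these readings, 1.63 for Pnmt and 0.83 for Ddc were among those at an unadjusted p under 0.05. The list had 6 members higher and 4 lower, with 0 past the threshold over all genes and 0 adjusted over the list alone. Its median was 0.08 and its mean 0.01, while camera pointed down (adjusted p = 0.901). The median was -0.02 after cyclic loess and -0.11 without sham 1 or without TAC 2.

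**Figure D1:**
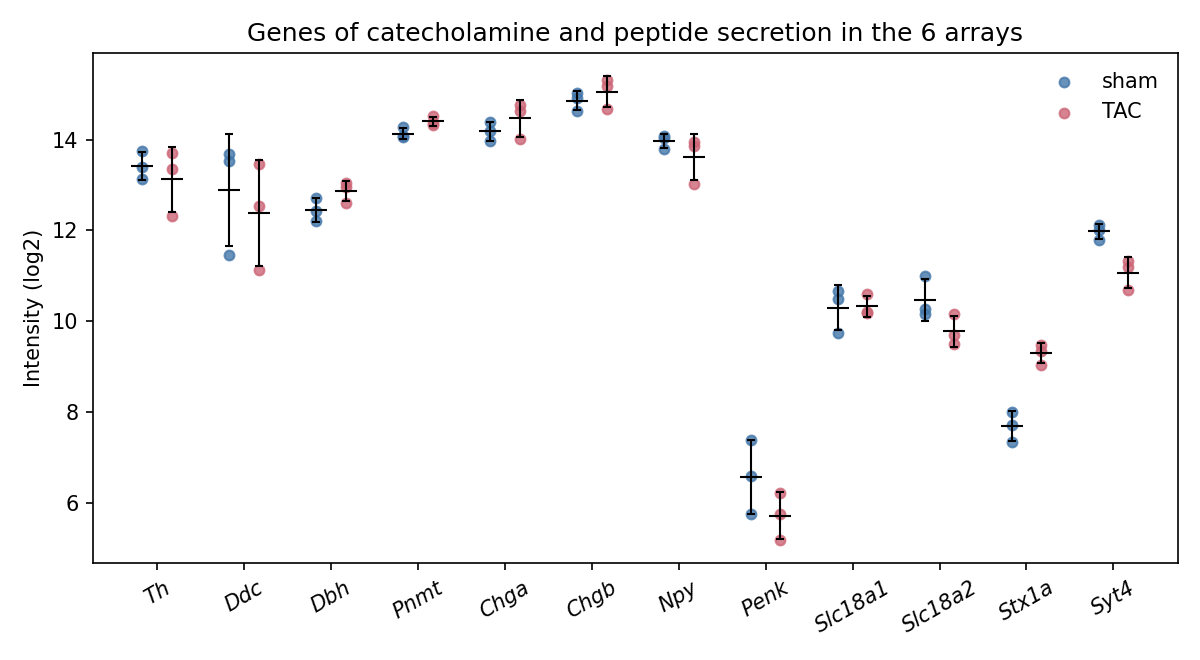
Log2 intensity (vertical axis) of 12 genes of catecholamine and peptide secretion in the 3 sham (blue) and 3 TAC (red) arrays, with points for arrays, horizontal bars for means and error bars for the SD. The groups overlap for Th, Ddc, Dbh, Chga, Chgb, Npy, Penk, Slc18a1 and Slc18a2, while those of Pnmt, Stx1a and Syt4 part without an adjusted p under the threshold over all genes.

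Storage and granule genes showed no shift as lists. In the list of catecholamine storage, uptake and breakdown, 4 of 8 members were higher (median -0.03, mean 0.05, camera down, adjusted p = 0.772). It held the vesicular transporters Slc18a1 (0.03 ± 0.32 SE) and Slc18a2 (-0.69 ± 0.33 SE, adjusted p = 0.787) and the proton pump subunit Atp6v0a1 (1.18 ± 0.32 SE, adjusted p = 0.508). Among granule proteins and prohormone processing genes 6 of 16 were higher (median -0.24, adjusted p = 0.470), with Chga at 0.29 ± 0.29, Chgb at 0.20 ± 0.27, Pcsk1n at 0.74 ± 0.28 and Cplx2 at 0.59 ± 0.26. Among neuropeptides and secreted hormones 2 of 7 were higher (median -0.33, adjusted p = 0.767), with Adm at 0.68, Pomc at 0.96, Npy at -0.36 and Penk at -0.86. Each of these 3 lists had 0 members past the threshold over all genes and 0 adjusted over the list alone. Their medians depended on single arrays. The storage median was 0.18 without sham 2, 0.11 without sham 3 and 0.22 without TAC 1. The granule median was 0.04 without TAC 1 and -0.45 without sham 1, and the neuropeptide median -0.01 without sham 2.

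In the exocytosis machinery, 16 of 26 measured genes were higher and 10 lower (median 0.08, camera up, adjusted p = 0.767), and the median was -0.02 after cyclic loess and also without sham 1. Stx1a, which encodes the plasma membrane fusion protein syntaxin 1A, measured 9.29 ± 0.22 after TAC and 7.69 ± 0.33 after sham, a 3.04-fold difference (1.60 ± 0.27 SE). Its adjusted p was 0.384 over all probe sets and 0.0249 adjusted over the list alone, the only 1 of the 26 under 0.05 there. The only tested probe set of Stx1a carries a suffix (x) that marks cross-hybridising probes. Syt4, a synaptotagmin of secretory vesicles, differed by -0.90 ± 0.27 (adjusted p = 0.552). Among voltage-gated ion channels 12 of 18 were higher (median 0.21, adjusted p = 0.780), with the median at 0.02 without sham 1, 0.04 without TAC 1, 0.10 without TAC 2, 0.33 without TAC 3 and -0.04 with array weights. Cacna1h, a T-type calcium channel gene, measured 5.42 ± 0.57 after TAC and was below the log2 4 filter in all sham arrays, so its computed difference of 1.66 is unreliable in size. Its adjusted p was 0.418 over all probe sets and 0.0448 over the list alone. With values under log2 4 set to 4 the difference was 1.42 ± 0.33 SE and the adjusted p over the list alone 0.0817, so that call rests on values near the floor. Cacna2d2 differed by -1.02 ± 0.30. Of the cholinergic receptor genes, through which splanchnic nerves drive secretion, 3 of 6 were higher (median 0.29, adjusted p = 0.767), among them Chrnb4 (1.09 ± 0.33 SE) and Chrnb2 (0.63 ± 0.37 SE). That median was 0.83 without TAC 1, 0.09 without sham 1 and -0.003 without TAC 2. In adrenergic and other receptor regulation 10 of 15 were higher (median 0.18, adjusted p = 0.858), with Gper1 at 0.86 and Grk6 at 0.78. This median was 0.05 without sham 1, without TAC 2 or with probe sets averaged, 0.29 without sham 2, 0.31 without TAC 1 and -0.003 without a filter. These 2 lists had 0 members past the threshold over all genes and 0 adjusted over the list alone.

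Chromaffin identity genes lay mostly above sham, at 12 of 16 members (median 0.25), and the list did not pass camera (adjusted p = 0.363), with 0 members past the threshold over all genes and 0 adjusted over the list alone. The transcription factor genes Hand2 (12.04 ± 0.20 against 11.30 ± 0.18, difference 0.74 ± 0.24 SE) and Hand1 (0.91 ± 0.34 SE) had the smallest p-values, with adjusted p-values of 0.584 and 0.682. The list median was 0.13 without TAC 3, 0.46 without TAC 1, 0.14 after quantile normalization or cyclic loess and 0.04 with probe sets averaged per gene. Without a filter on low values the list passed camera (median 0.23, camera adjusted p = 0.0243), and this call too was lost with an estimated correlation (adjusted p = 0.975).

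Connective tissue genes fell relative to the other genes in camera at its preset correlation, and these calls were lost with an estimated correlation. In the extracellular matrix list 17 of 23 members were lower (median -0.44, camera adjusted p = 0.00259, adjusted p = 0.963 with an estimated correlation). In the fibroblast list 8 of 11 were lower (median -1.11, camera adjusted p = 0.00259, adjusted p = 0.963 with an estimated correlation), and 5 of its measured members also belong to the matrix list. The fibrillar collagen genes Col3a1 (8.30 ± 0.83 after TAC, 9.97 ± 0.45 after sham, difference -1.67 ± 0.48 SE) and Col1a2 (-1.40 ± 0.43 SE) and the matrix gene Dpt (-1.11 ± 0.31 SE) were lower, and Pdgfrb, which encodes a receptor of mural cells and fibroblasts, was higher (0.81 ± 0.22 SE). These 4 of the 11 fibroblast members passed when adjusted over the list alone (limma adjusted p = 0.0471 for each), and over all genes 0 did, at adjusted p-values from 0.514 to 0.560. In the matrix list 0 members passed either way. Decorin (Dcn, chosen after its values were seen) read -2.38 ± 0.94 and Col1a1 (also chosen so) -0.27 ± 0.32. RNA integrity moved with these lists, since the mean of their 29 members was lowest within each group in the arrays with the largest Gapdh 3′ minus 5′ difference, at 7.23 in sham 1 and 6.94 in TAC 1, against 7.60 to 8.27 in the other 4. This was not particular to these lists. The median over all tested probe sets was also lowest within each group there, at 6.31 in sham 1 and 6.50 in TAC 1. So was the mean of the endothelial and smooth muscle members, at 6.11 and 5.93. Within the 3 arrays with the larger Gapdh difference (sham 1, TAC 1 and TAC 3) the median difference of TAC and sham was 0.07 for the matrix list and -0.02 for the fibroblast list, and within the other 3 arrays it was -0.23 and -0.85. In the same order, Col3a1 differed by -1.38 and -1.48, Col1a2 by -1.18 and -1.22, Dpt by -0.80 and -1.02, and Pdgfrb by 0.76 and 0.93. The groups did not overlap for these genes, so their sign could not differ between the parts. The sign was the same in both for 81.8% of fibroblast and 60.9% of matrix members, against 68.1% of all tested probe sets. These parts do not hold RNA integrity equal, and each sets a single array of one group against the rest. The Gapdh difference was 5.15 in sham 1 against 4.71 in TAC 1 and 3.98 in TAC 3. In the other part it was 3.67 in TAC 2 against 3.08 in sham 2 and 2.88 in sham 3. The matrix call was lost without sham 3 and TAC 1 together, the arrays with the most cortex signal, where its median was -0.03 (camera adjusted p = 0.075). Both calls were lost with array weights although the medians were larger there, at -0.55 (camera adjusted p = 0.128) for the matrix and -1.23 (camera adjusted p = 0.062) for the fibroblast list. The medians moved with single arrays while the calls held. The matrix median was -0.18 without TAC 1, -0.28 without sham 3, -0.67 without sham 1 and -0.70 without TAC 2, and the fibroblast median was -0.71 without TAC 1. The fibroblast median was -0.27 without a filter on low values and -0.57 without sham 3 and TAC 1 together.

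The ganglion neuron list also fell in camera, with 9 of 11 members lower (median -0.45, camera adjusted p = 0.00259, adjusted p = 0.963 with an estimated correlation). Map2, a dendritic microtubule protein gene, measured 9.25 ± 0.34 against 10.08 ± 0.45 (-0.83 ± 0.33 SE, limma adjusted p = 0.706), and Tubb3, a neuronal tubulin gene, differed by -0.45 ± 0.27 (adjusted p = 0.882). No member passed over all genes (0 of 11) or adjusted over the list alone (0 of 11). The median was -0.50 within the 3 arrays with the larger Gapdh difference and -0.33 within the other 3. The list median was -0.80 without TAC 2 and -0.90 without sham 1. The call was lost without sham 1 (camera adjusted p = 0.0646), with array weights (median -0.72, camera adjusted p = 0.128) and with a filter at a mean of log2 6 (median -0.40, camera adjusted p = 0.219). Without sham 3, 5 lists passed in place of 3, the added ones being the immediate early genes (median -0.26, camera adjusted p = 0.000545) and the glucocorticoid-induced genes (median -0.24, camera adjusted p = 0.0203), and with an estimated correlation 0 lists passed there.

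**Figure D2:**
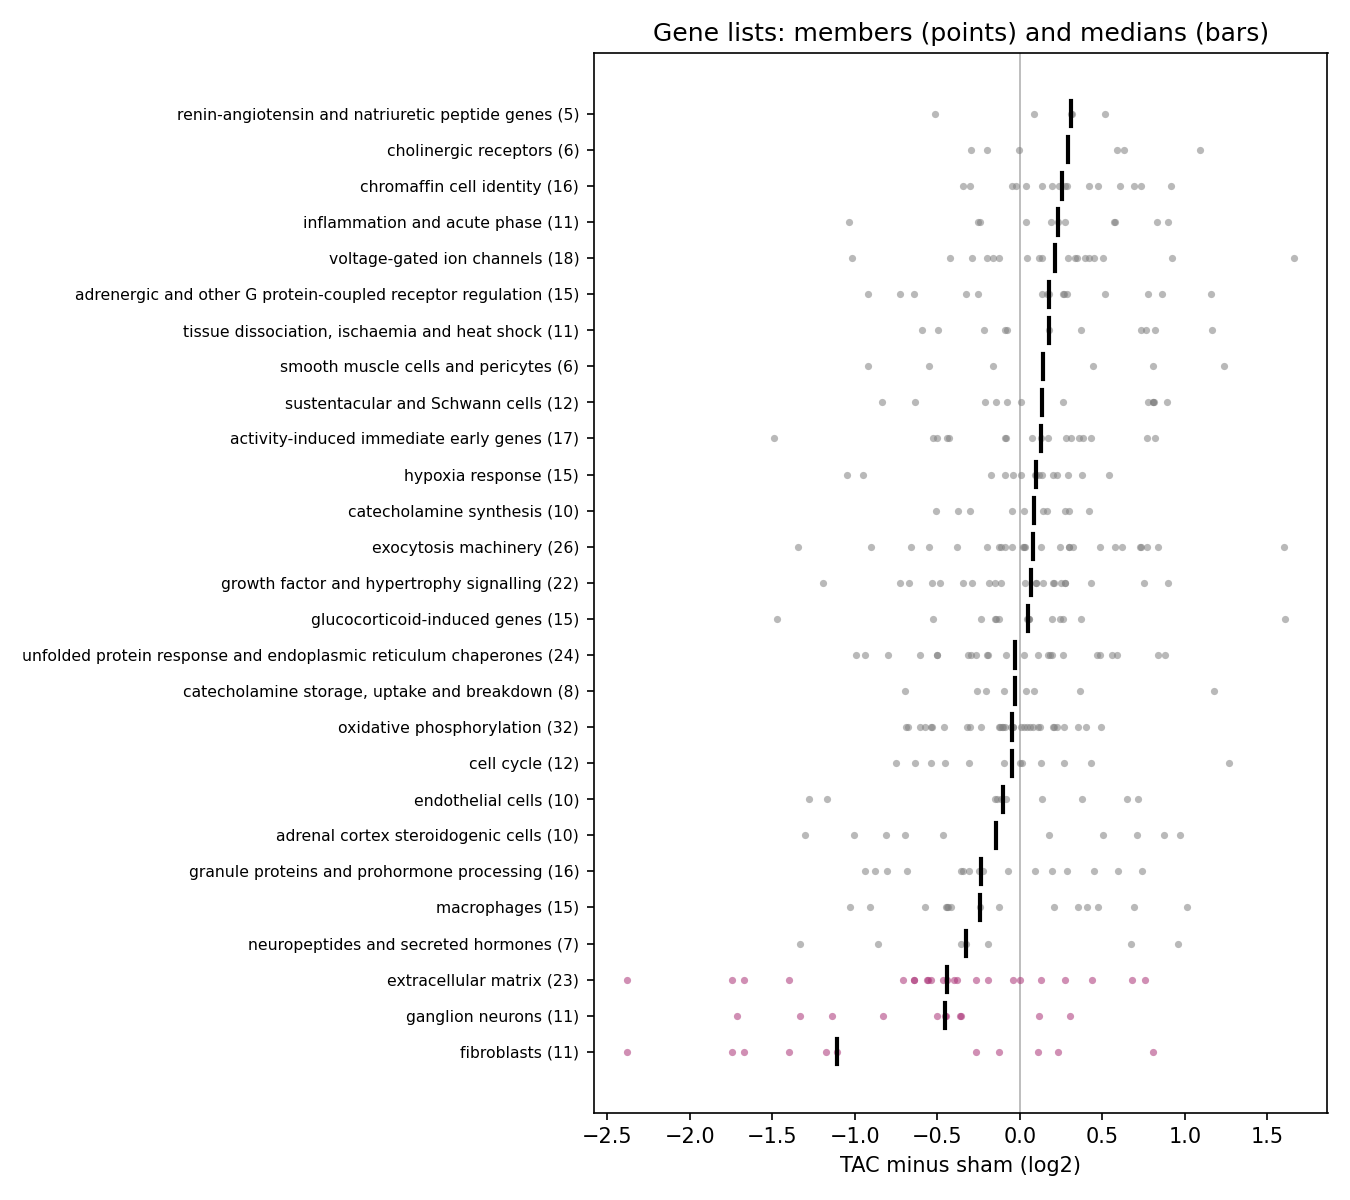
Difference of TAC minus sham (horizontal axis, log2) for the members of the 27 tested gene lists, with 1 point per gene, a black bar at each list's median and the number of measured genes in brackets. The lists past camera at its preset correlation are in purple, with medians of -1.11 (fibroblasts), -0.45 (ganglion neurons) and -0.44 (extracellular matrix), none of them past it with an estimated correlation.

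Other cell types did not pass camera. Macrophage genes were higher in 6 of 15 (median -0.24, adjusted p = 0.772), although the receptor gene Csf1r, which marks macrophages, measured 10.64 ± 0.28 against 9.63 ± 0.17 (1.01 ± 0.25 SE, limma adjusted p = 0.475) and the complement gene C1qb 0.69 ± 0.35. Sustentacular and Schwann cell genes were higher in 7 of 12 (median 0.13, adjusted p = 0.767), with the glial transcription factor gene Sox10 at 0.77 ± 0.24 and L1cam at 0.81 ± 0.27. Endothelial genes were higher in 4 of 10 (median -0.10, adjusted p = 0.767), with Eng at 0.72 and Tek at -1.17. Smooth muscle and pericyte genes were higher in 3 of 6 (median 0.14, adjusted p = 0.767), with Notch3 at 1.24 (its sham values all below log2 4, and 0.62 with such values set to 4), and passed the mixed form of fry, which asks for change in either direction (adjusted p = 0.0162). Fry was not repeated under other settings, so that call was not checked with low values set to 4. All of these lists had 0 members past the threshold over all genes and 0 adjusted over the list alone. Leaving out 1 array changed the sign of each of the 4 medians. Without TAC 1 they were 0.23 for macrophages and 0.37 for endothelium, without TAC 2 -0.10 for sustentacular and Schwann cells, and without TAC 3 -0.15 for smooth muscle. The lymphocyte list (4 measured members, Ptprc 0.28 and Gzma 0.25), the adipocyte list (4 members, Lpl -0.24 and Cox8b -0.39) and the red blood cell list (1 member, Bpgm -1.06) were too short to test.

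Signalling and stress lists did not pass camera, and none of them had a member past the threshold over all genes (0) or adjusted over the list alone (0). Immediate early genes, which respond to cell activity, were higher in 10 of 17 (median 0.13, mean 0.01, camera down, adjusted p = 0.767), with Jund at 0.77 and Nr4a3 at -1.49 (-1.09 with 1 TAC value under log2 4 set to 4). Glucocorticoid-induced genes were higher in 9 of 15 (median 0.05, camera down, adjusted p = 0.767), with Tsc22d3 at -1.47 ± 0.46 and Zbtb16 at 1.61 ± 0.61, and their median was -0.02 after quantile normalization and -0.06 after cyclic loess. Chaperone and unfolded protein response genes were higher in 12 of 24 (median -0.03, adjusted p = 0.767), with Calr at 0.88 ± 0.22 and Ern1 at 0.84 ± 0.25. Oxidative phosphorylation genes were higher in 14 of 32 (median -0.05, adjusted p = 0.304), with Uqcrc2 at -0.46 and Ndufb8 at 0.49. Hypoxia genes were higher in 10 of 15 (median 0.10, mean -0.01, camera down, adjusted p = 0.858), with Pdk1 at 0.54 and Ddit4 at -1.05, and their median was -0.01 after cyclic loess. Growth factor and hypertrophy genes were higher in 12 of 22 (median 0.07, mean -0.05, camera down, adjusted p = 0.618), with Egf at 0.75 and Igf1r at -0.48, and cell cycle genes in 5 of 12 (median -0.05, adjusted p = 0.470), with Mcm4 at 0.43 and Prc1 at -0.75. The growth factor median was -0.02 after cyclic loess, and the cell cycle median 0.00 after quantile normalization. Inflammation genes were higher in 8 of 11 (median 0.23, adjusted p = 0.767), with Socs3 at 0.83 and Icam1 at 0.57, and renin-angiotensin and natriuretic peptide genes in 4 of 5 (median 0.31, adjusted p = 0.767), with Agtr1a at 0.52 and Npr2 at 0.32. Heat shock and dissociation genes were higher in 6 of 11 (median 0.17, adjusted p = 0.772), with Hspa1a at 1.17 ± 0.32 and Bag3 at -0.59. Leaving out 1 array changed the sign of all these medians except those of the inflammation list (0.07 without sham 1 to 0.73 without TAC 1) and the renin-angiotensin list (0.04 without TAC 2 to 0.47 without TAC 1). They ran from -0.26 without sham 3 to 0.46 without sham 2 for immediate early genes, from -0.24 without sham 3 to 0.17 without sham 2 for glucocorticoid-induced genes, and from -0.31 without sham 1 to 0.24 without TAC 1 for chaperones. The other medians ran from -0.26 without sham 1 to 0.31 without TAC 1 for hypoxia, from -0.17 without TAC 2 to 0.40 without TAC 1 for heat shock, and from -0.27 without sham 1 to 0.20 without TAC 1 for oxidative phosphorylation. The growth factor median was -0.05 without TAC 1 and the cell cycle median 0.07 without sham 3. Without sham 3 camera called the immediate early and glucocorticoid-induced lists, and both calls were lost with an estimated correlation (adjusted p = 0.992). Without TAC 3 it called oxidative phosphorylation (median -0.08, camera adjusted p = 0.0496), a call lost with an estimated correlation (adjusted p = 0.966).

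Adrenal cortex markers varied between arrays and did not part the groups. The mean of 10 steroidogenic genes was 7.71 ± 1.11 (SD) after TAC and 7.81 ± 1.71 after sham, a difference of -0.10 (exact 2-sided permutation test, p = 1, the smallest possible being 0.1). It was 0.86 without sham 3, 0.45 without TAC 3, -0.39 without sham 1, -0.77 without sham 2 and -0.65 without TAC 1. The cortex list had 5 members higher and 5 lower (median -0.14, camera adjusted p = 0.772), with 0 past the threshold over all genes and 0 adjusted over the list alone. Without sham 2 the list passed camera (median -0.82, camera adjusted p = 0.0236) and not with an estimated correlation (adjusted p = 0.973), and without sham 3 its median was 0.89. Cyp11a1, which starts steroid synthesis, ranged from 3.22 in TAC 3 to 11.10 in sham 3, and Star, the cholesterol carrier, from 6.10 to 10.81 in the same arrays. Star differed by -1.01 ± 1.25 SE and Cyp11b1, the last enzyme of corticosterone synthesis, by -0.70 ± 1.26 SE, while Inha was at 0.97 and Fdx1 at 0.71.

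The 3′ minus 5′ difference of the Gapdh controls was 4.12 ± 0.53 after TAC and 3.70 ± 1.26 after sham (difference 0.42, exact 2-sided permutation test, p = 0.6), and that of beta-actin 5.70 ± 1.13 and 5.06 ± 2.51 (difference 0.64, exact 2-sided permutation test, p = 0.7). The Gapdh difference between groups was 1.14 without sham 1 (exact permutation p = 0.1, the smallest possible), 0.11 without sham 2, 0.12 without TAC 1, 0.64 without TAC 2 and 0.00 without sham 3. The first principal component held 69.2% of the variance and put sham 1 (103.4) and TAC 1 (80.0) far from sham 2 (-66.4), sham 3 (-66.9) and TAC 2 (-69.5), with TAC 3 at 19.4, so the groups overlapped on it. Scores on this component correlated with the Gapdh difference over the 6 arrays (Pearson r = 0.948, exact permutation p = 0.00694, 0.0208 adjusted over 5 measures, and Spearman rho = 0.829, exact permutation p = 0.0583, 0.128 adjusted). Without sham 1 and sham 3, the arrays farthest from the median, r was 0.920. For beta-actin r was 0.965 (exact permutation p = 0.00833, 0.0208 adjusted) and rho 0.771 (exact permutation p = 0.103, 0.128 adjusted), and r was 0.974 without sham 1 and sham 2. For the cortex mean r was -0.074 (exact permutation p = 0.890) and rho -0.20 (exact permutation p = 0.714). The second component held 16.5% and parted the groups, with TAC scores from 24.9 to 44.4 and sham scores from -43.3 to -28.5 (exact 2-sided permutation test, p = 0.1, the smallest possible).

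**Figure D3:**
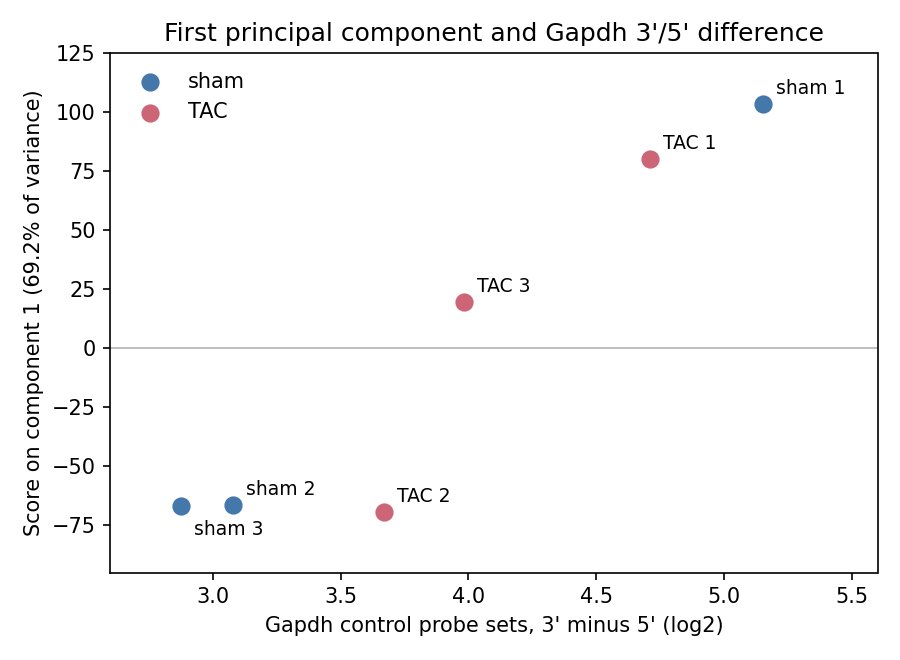
Score of each array on the first principal component (vertical axis, 69.2% of the variance) against the log2 difference of the 3′ and 5′ Gapdh control probe sets (horizontal axis), with 1 point per array, sham in blue and TAC in red. Scores are higher where the Gapdh difference is larger (r = 0.948), and both groups span positive and negative scores.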

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

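The settings that left out sham 1 and TAC 1 or sham 3 and TAC 1 together, added the Gapdh 3′ minus 5′ difference as a covariate, or used RNA integrity as a block were chosen after seeing the data, and all others before. The count of 0 probe sets past an adjusted p of 0.05 held in limma under every setting except array weights, with 6698 (2762 higher), and the count at an unadjusted p under 0.05 with at least a 1.5-fold difference was 1232. Only the Gapdh covariate (839), the block on the 3 arrays with the larger Gapdh difference (88) and array weights (8633) gave probe sets under 0.10. Against 1263 at an unadjusted p under 0.05, the count was 2110 without a filter and 644 with probe sets averaged per gene, which test other numbers of features, 8749 with array weights, 814 with the cortex mean as covariate, 3843 with the Gapdh covariate, 3173 with sham 1 and TAC 1 as a block and 4007 with the block on the 3 arrays with the larger Gapdh difference. It was 2507 without sham 1 and TAC 1, 640 without sham 3 and TAC 1, and from 641 to 2429 with 1 array left out. Against 3 lists past camera, 0 passed with array weights, 0 with an estimated correlation and 0 in fry outside its mixed form, and 2 to 5 did with 1 array left out. The mixed form of fry, run in the main setting only, gave 1. The matrix call held in 20 of 22 settings, the fibroblast call in 21 and the ganglion call in 19. The catecholamine synthesis median, 0.08, was -0.0193 after cyclic loess, -0.00865 with probe sets averaged, -0.0689 with array weights and from -0.109 to 0.224 with 1 array left out. The cortex difference was 0.306 without sham 3 and TAC 1 and from -0.774 to 0.855 with 1 array left out, and the Gapdh difference, 0.418, was -0.29 without sham 3 and TAC 1, 0.848 without sham 1 and TAC 1 and from 0.00454 to 1.14 with 1 array left out. Over 1962 values of 90 named genes, 49 had another sign than the main value, 1 of them in the first part of the naming rule. That part required groups without overlap, so leaving out arrays could not change the sign of its genes. Its low count therefore does not measure robustness. The cause of the moves between settings was not tested. Arrays with the same replicate number deviated together in pairs 1 and 2 (r = 0.764 and 0.783) and not in pair 3 (r = -0.215). The labels state no pairing, and these values cannot tell whether the numbers pair the animals. The replicate block gave 3005 probe sets at an unadjusted p under 0.05 and 0 past the threshold. GCRMA intensities near the floor leave little signal over background, and Adra2c and Cyp11b2 have no test for that reason.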

Other observations

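The tests of the first principal component, of cortex carry-over as the whole cause and of namings of the arrays were chosen after their results were seen. The others were chosen before their own results, those of the lower matrix and fibroblast lists after that pattern had been seen. Some genes changed sign between probe sets that both had an unadjusted p under 0.05, at 13 of the 77 genes with 2 or more such probe sets. Among these 13, chosen after their values were seen, were the myosin gene Myh9, the histone demethylase gene Kdm6b, the G protein subunit gene Gnai2 and the coactivator gene Crebbp. Probe sets with a suffix x, s or a were higher after TAC in 77.5% of those without overlap between groups, against 64.2% of the plain ones. After cyclic loess the shares were 48.9% and 46.0%. The suffix x marks cross-hybridising probes, s probes shared by transcripts of different genes, and a probes shared by transcripts of the same gene. These classes were not counted apart, so the shares are not a measure of cross-hybridisation. In the first part of the naming rule such probe sets stood for Rhof (x), Phc2 (x), Kcnh2 (a), Sf3a2 (s), Srebf1 (a) and Pkdcc (s) among the higher genes. Among the lower genes they stood for Rbfox2 (a) and Cldnd1 (a). With the block on the 3 arrays with the larger Gapdh difference, chosen after seeing the data, Stx1a differed by 1.46 ± 0.19 SE (limma adjusted p = 0.097) and Atp6v0a1 by 1.38 ± 0.19 SE (limma adjusted p = 0.097), neither past the threshold.

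Most of the spread between arrays lay on a component that put sham 1 and TAC 1 together. Aortic constriction is argued against as its source, since the groups overlapped on it (exact 2-sided permutation test of the group means, p = 1). A candidate explanation is RNA integrity, because the smaller of the correlations of its scores with the Gapdh and beta-actin 3′ minus 5′ differences was 0.948. Lower RNA input stays open, as the scores also followed the poly-A spike-in controls (r = 0.767, exact permutation p = 0.0542, 0.0677 adjusted over 5 measures, Spearman rho = 0.829, exact permutation p = 0.0583, 0.128 adjusted, and r = 0.913 without sham 2 and TAC 2), with a lowest r of 0.723 when 1 array was left out. The hybridisation controls, added after amplification, followed them as well (r = 0.868, exact permutation p = 0.0486, 0.0677 adjusted, Spearman rho = 0.771, exact permutation p = 0.103, 0.128 adjusted, and r = 0.810 without sham 1 and sham 3).

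The differences between TAC and sham cannot be told apart from unequal RNA quality with 6 arrays. Across probe sets, which are not independent replicates, they correlated with each probe set's slope on the Gapdh difference within groups at r = 0.232, which ranged from -0.158 to 0.600 with 1 array left out. Cortex carry-over gave r = -0.0859 with the slope on the cortex mean (from -0.136 to 0.218 with 1 array left out). The value with all arrays met the outcome set in advance as against carry-over, while the lowest with 1 array left out did not. Leaving arrays out was not part of that outcome. Slope times group difference gave an SD across probe sets of 0.0136 against 0.534 seen. That ratio, 0.0255, argues for at most a small part, but it reached 0.623 with 1 array left out (for the Gapdh difference it was 0.469, and 0.0054 to 1.5), so carry-over stays open. With the arrays parted into 3 and 3 by the Gapdh difference, the TAC minus sham differences of the parts correlated at r = 0.470 across probe sets, the highest of 9 ways to name 1 sham array in one part and 1 TAC array in the other (1 of 9, highest other 0.291). A difference that goes with the surgery may be part of these values, and 9 namings are too few to exclude chance.

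The lower matrix and fibroblast genes after TAC averaged -0.41 over 29 members, and none of the explanations tested could be excluded. The test of RNA integrity, a mean of -0.474 without sham 1 and TAC 1, met the outcome written before that result as against that cause. The pattern and the arrays left out were themselves chosen after seeing the data. This test was set aside after the result was seen and decides nothing, because the Gapdh difference between groups was 0.848 there against 0.418 with all arrays. RNA integrity stays open, as the mean was 0.045 ± 0.123 (SE across the 29 members, not between animals) without sham 3 and TAC 1. It was -0.187 ± 0.130 with the Gapdh covariate and -0.130 ± 0.129 with the block on the 3 arrays with the larger Gapdh difference (settings chosen after seeing the data). That block did not make the Gapdh difference equal within its parts, and without sham 3 and TAC 1 the Gapdh difference between groups was -0.29. Without sham 3 alone it was 0.005, with a mean of -0.234 ± 0.133. Without sham 2 it was 0.106, with a mean of -0.254 ± 0.136. Less connective or vascular tissue in the TAC samples stays open, with 15 endothelial and smooth muscle members at a mean of -0.0665, above the matrix and fibroblast members by 0.347 ± 0.231 (SE across members, not between animals). A single array as the source also stays open, since the mean was between -0.753 and -0.234 with 1 sham array left out and -0.134 without TAC 1, and an effect of the constriction itself is untested beyond the comparison of the groups.

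The 10 splits of the 6 arrays into 3 and 3 are too few for a share under 0.05. The real split gave 0 probe sets past the threshold and the highest other 4900. With a real count of 0, 10 of 10 had to give as many, so this count decides nothing. At an unadjusted p under 0.05 the real split gave 1263 and the highest other 7856, with 2 of 10 as large. For lists past camera the real split gave 3 and the highest other 6, with 5 of 10 as large. The split with 4900 and 7856 set sham 1, TAC 1 and TAC 3 against the other arrays, which is the order of the Gapdh difference, and points to a structure of the samples other than the surgery. With that split as a block, TAC against sham gave 0 probe sets past the threshold and 4007 at an unadjusted p under 0.05.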
